A study of Homo sapiens with 6 samples.

How the data were processed

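PolyA RNA of MDA-MB-231 cells, an established human cell line from a triple-negative breast cancer, was measured by RNA sequencing after 1 hour with 25 µM roscovitine or with DMSO, the solvent control. Libraries were prepared from total RNA with an Illumina TruSeq kit, per the labels' protocols. There were 3 libraries per treatment, and each was assigned to its group by its treatment label. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The series' design text speaks of duplicates, whereas 3 libraries per treatment are listed. The treatment label also mentions erythroid differentiation, which is why markers of erythroid cells were among the gene lists.

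The authors deposited a table of 32428 genes with FPKM values (fragments scaled to transcript length and to the mapped fragments of the library) for each of the 6 libraries, per the file headers. The same deposited table holds the authors' fold ratio of the mean FPKM with roscovitine over that with DMSO, its log2 value, and the p-value and q-value of the authors' own test, per the file headers. The submitters' processing notes name CASAVA 1.8, Trimmomatic, FastQC, HISAT2, RSEM and edgeR and the genome build GRCh38, without roles, whereas the series' design text names other aligners and tests. Which of these tools produced the FPKM values is therefore open. FPKM was already scaled by the authors for library size and transcript length, so a transcript that takes a large share of a library lowers the values of all others. The table also carries KEGG and gene ontology annotation, of which 2213 gene ontology cells and 6 KEGG cells were not used here.

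Read counts were not used here, so the count-based tests of the design gave way to the test named for FPKM values. Depth was looked for in the low values. Among genes with a single transcript, the most repeated product of FPKM and transcript length gave the worth of 1 fragment. By this measure relative depth lay between 90.4% and 100% of the deepest library. The search was confined to the same narrow range of products in every library, so it could not show a large difference in depth. Only 8.31% to 9.84% of values up to 20 fragments lay within 2% of 1 fragment from a whole multiple, so reads were not recovered and the relative depth is uncertain. The absolute depth is unknown and no counting interval is given.

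FPKM values were transformed as log2(FPKM + 1), with a pseudocount of 1, and genes with at least 1 FPKM in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3, using an intensity-dependent prior variance and no covariate. Log2 fold changes are on this scale, which understates the change of genes with low values. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The gene lists, 31 in number, were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01 when at least 5 members were tested. The same test with an estimated correlation and limma's fry, which asks whether a list's own genes move one way on balance, were run beside it. The list result is the median log2 fold change of its members minus that of all tested genes.

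The design, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule takes the 12 genes with the smallest p in each direction among those with an absolute log2 fold change of at least 0.58, a mean of at least 5 FPKM in the higher group, no overlap between the groups and a symbol that is not a clone name. It adds 12 fixed genes (TRIM32, STAT3, CDK1, CDK2, CDK5, CDK7, CDK9, MCL1, MYC, HEXIM1, SOCS3 and CDKN1A) and up to 4 members with the smallest p per list. One gene that the rule takes is not reported here. Since no gene passed the adjusted threshold, the genes of the first part are given as values only. Gene coordinates are those of GENCODE release 29 on GRCh38, 1-based, matched by Ensembl identifier; the release used by the authors is not given in the sources used here.

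The first set of alternatives held another pseudocount, no filter and a stricter filter on low values, the replicate number as a block, each library left out in turn, an adjusted threshold of 0.01 and the estimated correlation. Ranges of a list's adjusted p over the alternatives were taken at the preset correlation, except that of the lysosome pathway, which includes the estimated one. Alternatives added after the data were seen were other scalings, library weights, a robust prior, removal of length and GC trends, leaving out the second library of each treatment and, for the lists past the threshold, filters of 1 FPKM in all 6 libraries or in their mean. The code was tested on simulated data for the 11733 genes of the roscovitine and DMSO comparison, with independent noise at each gene's own spread and 200 changed genes above 5 FPKM. It recovered 32% of 100 genes changed 2-fold and 81% of 100 genes changed 4-fold at the adjusted threshold, with 4 unchanged genes called. In the same simulation, a list of 30 genes shifted by 0.5 on the log2 scale gave a camera p of 1.84e-19 and an unshifted list a p of 0.913. Simulated genes varied independently, whereas the estimated correlation in the data reached 0.84 for mitochondrially encoded mRNAs and 0.87 for cytosolic ribosomal proteins. The simulation therefore cannot show how often camera calls unshifted lists in these data.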

Results

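RNA was profiled in MDA-MB-231 cells, a human triple-negative breast cancer line, after 1 hour with 25 µM roscovitine or with DMSO. Roscovitine is a purine-based small molecule that inhibits cyclin-dependent kinases, including those that drive the cell cycle and those that phosphorylate RNA polymerase II. Each treatment had 3 libraries of polyA RNA, and expression was given as FPKM. The title of the series places the work in the context of TRIM32, a ubiquitin ligase, its entry into the nucleus, and STAT3 signalling. RNA levels do not measure where a protein is located, so the comparison below concerns transcripts only.

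The summed FPKM of the libraries lay between 274940 and 352550, and 10934 to 11730 genes reached 1 FPKM in each. Mitochondrially encoded genes took 38.2%, 37.7% and 45.8% of the summed FPKM in the roscovitine libraries and 25.1%, 33.8% and 26.3% in the DMSO libraries. The group means were 40.6% ± 4.53 with roscovitine and 28.4% ± 4.73 with DMSO (SD, n = 3), a difference of 12.2 percentage points. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. The second library of each treatment stood apart from the rest, that of roscovitine furthest. The mean correlation of the second roscovitine library with the other roscovitine libraries was 0.909 on the log2 scale, against 0.939 to 0.961 for the other 5 libraries within their groups. It lay at 60.0 on the first principal component, which held 50.3% of the variance, where the second DMSO library lay at the other end, at -35.9, and the other 4 between -10.9 and 3.51. The second DMSO library also lay at -29.0 on the third component, which held 14.5% of the variance, where the others lay between -11.6 and 16.6. The second component, with 25.3% of the variance, placed all roscovitine libraries below 0 and all DMSO libraries above 0. However, roscovitine replicate 2, at -4.45, and DMSO replicate 2, at 0.404, lay close together on it. The other roscovitine libraries lay at -28.5 and -19.4 and the other DMSO libraries at 30.3 and 21.6. Roscovitine replicate 3 had a mean correlation of 0.950 with the DMSO libraries and of 0.944 with the other roscovitine libraries. The other 5 libraries correlated better with their own group.

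**Figure D1:**
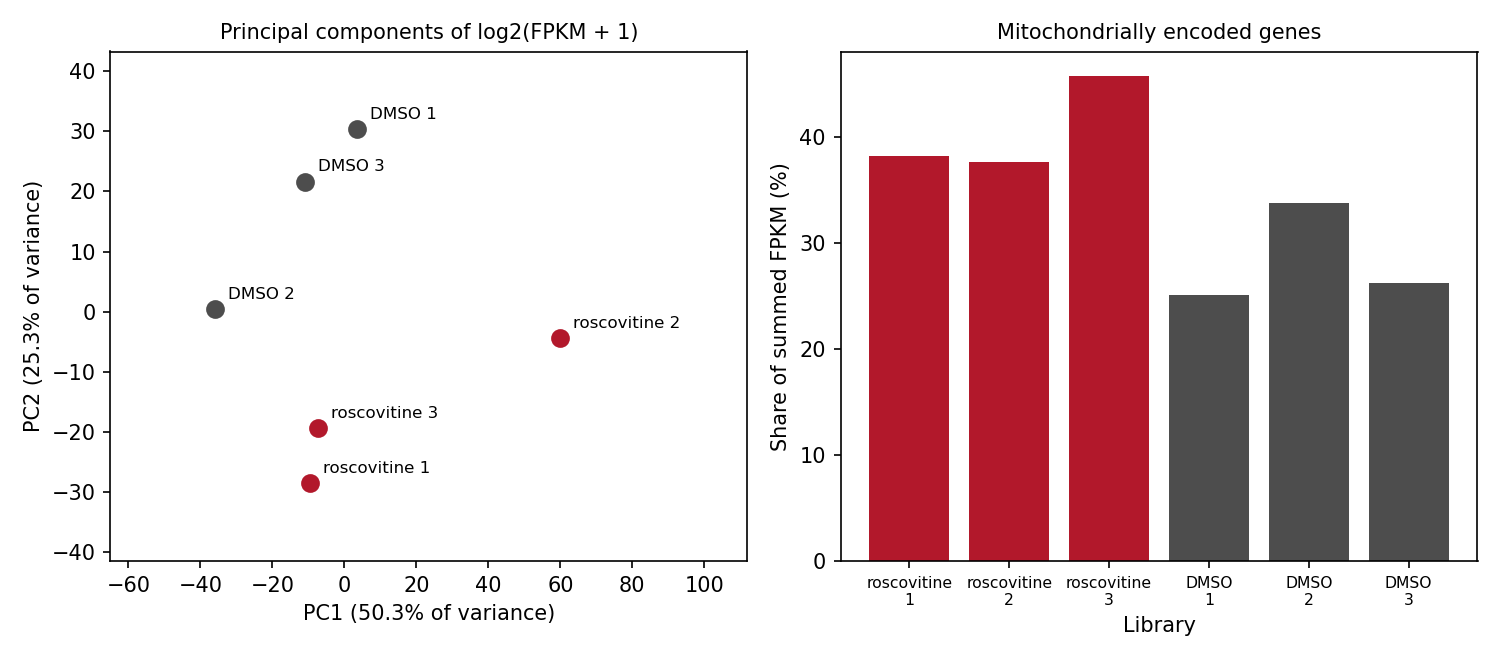
Left, the first and second principal components of log2(FPKM + 1) for the 6 libraries, with the share of variance on each axis. Right, the share of summed FPKM taken by mitochondrially encoded genes, one bar per library: the roscovitine libraries lie at 37.7% to 45.8% and the DMSO libraries at 25.1% to 33.8%.

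Mitochondrially encoded mRNAs, mRNAs of cholesterol synthesis enzymes, histone mRNAs past the filter on low values and mRNAs of the NRF2 and metal response rose with roscovitine relative to all tested genes. The histone list was not called by camera when the filter was removed. Cytosolic ribosomal protein mRNAs fell relative to all tested genes. FPKM values are shares of a library, so a list's rise cannot be told from a fall of the other genes, or the reverse. All 5 of these list results came from camera with its preset correlation, and 0 of them passed with an estimated one. With the preset correlation camera also called lists in every other split of the 6 libraries into 3 and 3, up to 18. The real grouping called no more lists than any other split. By fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, 0 of 29 lists passed. Among the single genes named by smallest p, UCA1, ADORA2A and TRIM29 had the largest log2 fold changes above 0 with roscovitine and F2RL1, ADAM19 and EMP1 the largest below 0, between -2.22 and 2.80 with no overlap between the groups. No single gene passed the adjusted threshold.

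UCA1, a long non-coding RNA first described in bladder cancer, had the largest log2 fold change among the genes named by rule, at 2.80 ± 0.47 (SE) on log2(FPKM + 1). It was at 164 ± 125 FPKM with roscovitine and 19.2 ± 4.47 with DMSO (SD, n = 3). By the authors' ratio of mean FPKM, ADORA2A had a larger log2 value, 3.22 against 3.1 for UCA1. The UCA1 gene lies on chromosome 19, 15828206 to 15836326, forward strand (ENSG00000214049, GRCh38). EPHX1, which encodes the microsomal epoxide hydrolase (ENSG00000143819, chromosome 1, 225810092 to 225845563, forward strand), was at 68.9 ± 18.8 FPKM against 19.8 ± 3.91, with a log2 fold change of 1.73 ± 0.26. The transcription factor gene PAX8 was at 8.43 ± 3.15 against 1.74 ± 0.71 FPKM, and the TRIM family gene TRIM29 at 10.4 ± 4.33 against 1.95 ± 0.737. The cell-surface proteoglycan genes SDC3 and GPC1 had log2 fold changes of 1.21 ± 0.18 and 1.12 ± 0.19. The adenosine receptor gene ADORA2A was at 9.09 ± 2.83 against 0.978 ± 1.44 FPKM and the cystatin gene CST7 at 16.5 ± 2.36 against 4.27 ± 1.88. The monoamine oxidase gene MAOB was at 9.38 ± 4.19 against 2.21 ± 0.446 FPKM. SLC9A3R1 and ANKRD52 had log2 fold changes of 1.13 ± 0.19 and 0.98 ± 0.19. The adjusted p of these 11 genes by limma lay between 0.156 and 0.158.

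ADAM19, a membrane-anchored metalloprotease gene (ENSG00000135074, chromosome 5, 157395534 to 157575775, reverse strand), was at 0.84 ± 0.24 FPKM with roscovitine and 6.17 ± 1.86 with DMSO (SD, n = 3), a log2 fold change of -1.94 ± 0.24 (SE). F2RL1, which encodes the protease-activated receptor PAR2 (ENSG00000164251, chromosome 5, 76818933 to 76835315, forward strand), was at 18.3 ± 9.17 against 83.2 ± 16.3 FPKM, a log2 fold change of -2.22 ± 0.36. The membrane protein gene EMP1 was at 18.6 ± 6.33 against 63.3 ± 7.54 FPKM. COL6A3, a collagen VI chain, and GALNT6, an enzyme that starts O-linked glycosylation, were at 1.16 ± 0.547 and 1.37 ± 0.464 FPKM with roscovitine against 5.26 ± 1.5 and 6.16 ± 2.09 with DMSO. SNAPC1, a subunit of a complex that binds the promoters of small nuclear RNA genes, was at 13.3 ± 4.59 against 39.1 ± 3.74 FPKM. The adhesion molecule gene CLMP was at 2.79 ± 1.42 against 10.8 ± 2.9 FPKM. MORC4, SUSD3, EI24, BZW2 and LRATD2 had log2 fold changes of -1.47, -1.29, -1.55, -1.11 and -1.56, with SEs of 0.20 to 0.29. For these 12 genes the limma adjusted p was again 0.156 to 0.158.

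**Figure D2:**
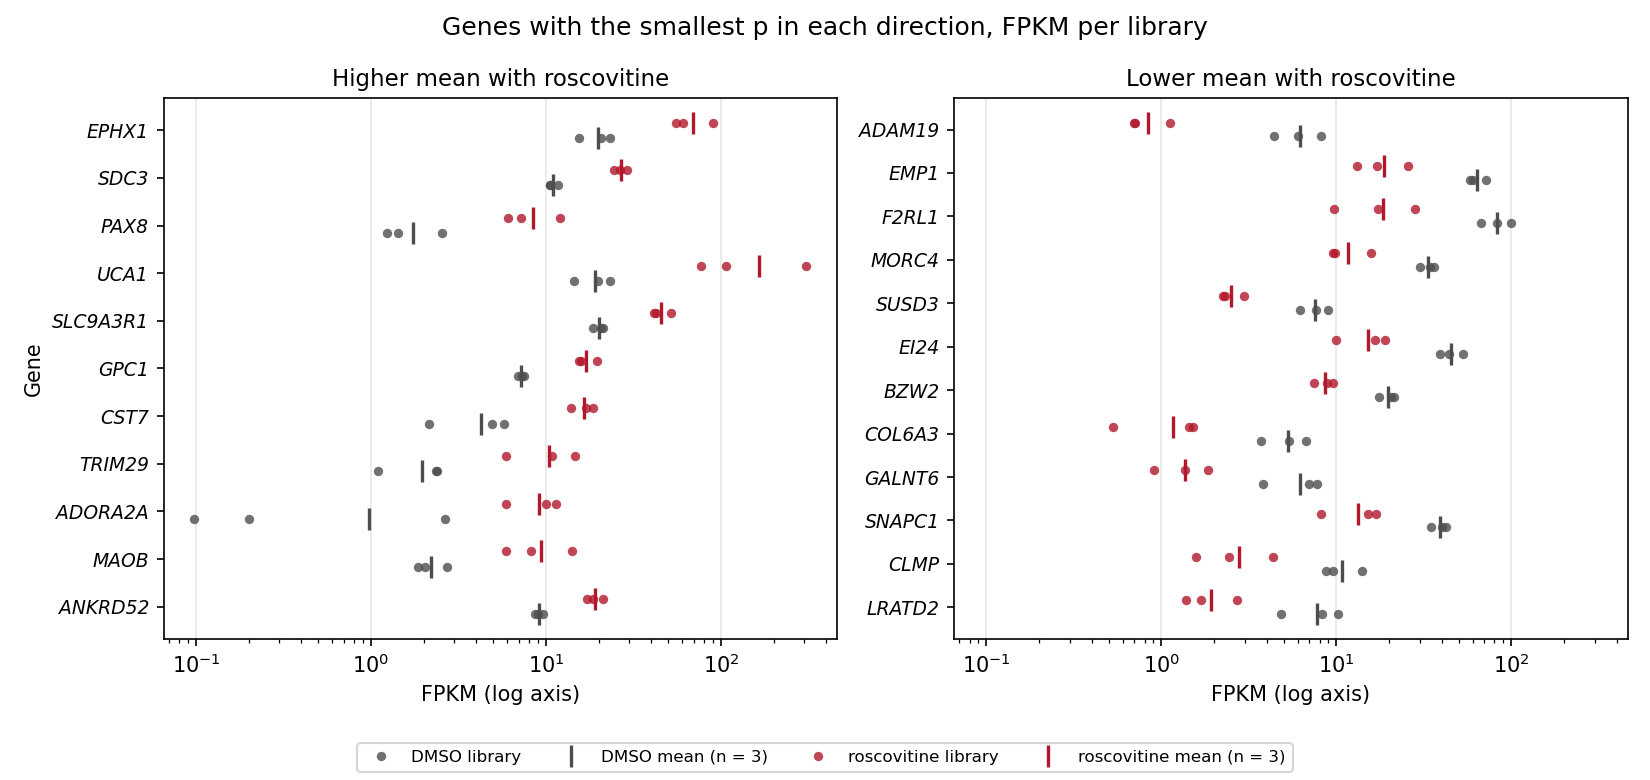
FPKM on a log axis of the named genes with the smallest p in each direction, 11 higher and 12 lower. Each point is a library and each tick the mean of 3 libraries, for roscovitine and DMSO; the groups do not overlap for any gene shown, with UCA1 at 77.4 to 308 FPKM with roscovitine and 14.5 to 23.4 with DMSO.

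Of 11733 genes tested with limma, 0 were higher and 0 lower at an adjusted p of 0.05, and the smallest adjusted p was 0.156. At an unadjusted p under 0.05, 543 genes were higher and 895 lower, 1438 in all where 587 are expected by chance. Genes do not vary independently, and a split of the 6 libraries that mixed the treatments gave 1794. It set roscovitine 1 and 3 with DMSO 2, and the remaining mixed splits gave 49 to 714. The excess over 587 alone therefore does not establish an effect of treatment. Every mixed split still held more libraries of one treatment than of the other on each side, so none was free of treatment. Without the first DMSO library, 340 genes were higher and 499 lower at an unadjusted p under 0.05. Without the third these counts were 342 and 479, and without the first roscovitine library 347 and 875. The groups did not overlap for 2480 genes, 21.1% of those tested where chance gives 10%, of which 966 were higher and 1514 lower. Higher values made up 37.8% of the genes at unadjusted p under 0.05, against 58.1% to 61.7% when the libraries were rescaled to the bulk of genes in 4 other ways, and the median log2 fold change of all tested genes moved from -0.12 to as far as -0.012. Limma with libraries weighted by their spread called 454 genes higher and 969 lower, and with the second library of each treatment left out it called 284 and 786. The weights of the second libraries were 0.164 and 0.418, so both of these fits rested largely on the same 4 libraries. Without the second roscovitine library 1 gene, AC023055, was lower with an adjusted p of 0.0291 by limma, and with length and GC trends removed 1 gene, PLEKHS1, was higher with an adjusted p of 0.0408. Both genes were chosen after their values were seen, and their adjusted p lay between 0.00499 and 0.629 for AC023055 over the 16 alternatives that tested it and between 0.00342 and 0.615 for PLEKHS1 over 13. PLEKHS1 was at 3.83 ± 0.453 FPKM with roscovitine and 0.745 ± 0.0509 with DMSO, whereas AC023055 was at 0.0186, 3.58 and 0.0405 FPKM in the roscovitine libraries and 5.59 ± 1.19 with DMSO.

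TRIM32 (ENSG00000119401, chromosome 9, 116687302 to 116701300, forward strand) was at 4.07 ± 0.144 FPKM with roscovitine and 5.1 ± 0.918 with DMSO, a log2 fold change of -0.26 (95% interval -0.71 to 0.20) and a limma adjusted p of 0.606. STAT3 (ENSG00000168610, chromosome 17, 42313324 to 42388568, reverse strand) was at 25.1 ± 3.47 against 18.3 ± 4.03 FPKM, a log2 fold change of 0.45 (95% interval -0.083 to 0.98) and an adjusted p of 0.467 by limma. SOCS3, a feedback inhibitor that STAT3 induces, was at 10.1 ± 6.2 against 9.23 ± 1.43 FPKM, with 17.3 in the second roscovitine library. Among the kinases that roscovitine inhibits, CDK1 had a log2 fold change of -0.49 ± 0.30 (SE), CDK2 of -0.17 ± 0.21, CDK5 of 0.026 ± 0.26, CDK7 of -0.15 ± 0.19 and CDK9 of 0.12 ± 0.22. The 95% interval of each of these 5 kinases included 0. MCL1, an anti-apoptotic gene with a short-lived mRNA, was at 37.5 ± 8.93 FPKM with roscovitine and 69.8 ± 9.47 with DMSO, without overlap, and its limma adjusted p was 0.219. MYC was at 19.4 ± 4.94 against 23.99 ± 5.28 FPKM. HEXIM1, an inhibitor of the CDK9 complex, was at 36.5 ± 3.2 against 33.4 ± 1.45, and the cell-cycle inhibitor CDKN1A at 21.1 ± 2.52 against 24.2 ± 3.89.

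Mitochondrially encoded mRNAs, the transcripts of the mitochondrial genome for respiratory chain subunits, rose relative to all tested genes. All 13 had a log2 fold change above that of the median gene, 8 had an unadjusted p under 0.05, and the list median lay 0.81 above that of all genes (camera adjusted p = 8.28e-10; adjusted p = 0.65 with an estimated correlation). MT-CO1 and MT-CO2, subunits of cytochrome oxidase, were at 19726 ± 3466 and 17822 ± 2354 FPKM with roscovitine against 10996 ± 2457 and 9642 ± 1717 with DMSO (SD, n = 3). MT-ND1, a subunit of NADH dehydrogenase, was at 4791 ± 474 against 2445 ± 478 FPKM. Because FPKM is a share of the library, a rise of these mRNAs cannot be told from a fall of the others. Under quantile normalization the list lay 0.14 above all genes, with a camera adjusted p of 0.366, in a range of 8.29e-14 to 0.366 over 20 alternatives. Nuclear-encoded subunits of oxidative phosphorylation, 40 genes, lay close to all genes (adjusted p = 0.605 by camera), and UQCRC2 was at 13.5 ± 1.3 against 19.2 ± 1.42 FPKM. This list lay at 0.0018 relative to all genes. Without the second roscovitine library camera called it lower, at -0.33 (camera adjusted p = 2.9e-06), as it did with library weights, at -0.31 (camera adjusted p = 5.71e-05), and without both second libraries, at -0.40 (camera adjusted p = 5.38e-07), in a range of 5.38e-07 to 0.754 over the alternatives.

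Genes of cholesterol synthesis and other targets of the SREBP transcription factors rose as a list. Of 28 members, 25 lay above the median gene and 4 had an unadjusted p under 0.05, and the list median lay 0.47 above all genes (camera adjusted p = 2.45e-05; adjusted p = 0.894 with an estimated correlation). Without the second DMSO library it lay 0.26 above (camera adjusted p = 0.0307, in a range of 1.06e-08 to 0.0307 over the alternatives at the preset correlation). LSS, which encodes lanosterol synthase, was at 45.99 ± 1.36 FPKM with roscovitine and 26.3 ± 4.1 with DMSO. The mevalonate kinase gene MVK was at 5.3 ± 0.0968 against 3.09 ± 0.459 FPKM, the fatty acid synthase gene FASN at 61.7 ± 5 against 40.03 ± 10.2, and DHCR7, which acts at the last step of cholesterol synthesis, at 52.9 ± 8.49 against 36.1 ± 4.63. The NRF2 and metal response list, which holds antioxidant, iron storage and metallothionein genes, also rose. Its median lay 0.40 above all genes, with 17 of 21 members above the median gene and 6 at an unadjusted p under 0.05 (camera adjusted p = 0.000166; adjusted p = 0.598 with an estimated correlation). The ferritin genes FTL and FTH1 were at 3125 ± 697 and 1277 ± 309 FPKM with roscovitine against 1314 ± 199 and 672 ± 195 with DMSO. SRXN1, which encodes sulfiredoxin, was at 40.8 ± 5.16 against 24.6 ± 4.81 FPKM, and the quinone reductase gene NQO1 was at 68.7 ± 14.5 against 39.96 ± 17.9, with overlap between the groups.

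Replication-dependent histone genes, whose main transcripts lack a polyA tail, rose as a list of 9 tested members, 8 of them above the median gene and 4 at an unadjusted p under 0.05. The list median lay 0.71 above all genes (camera adjusted p = 2.92e-05; adjusted p = 0.526 with an estimated correlation). H4C8 was at 1.39 ± 0.116 FPKM with roscovitine and 0.442 ± 0.0712 with DMSO, H2BC21 at 1.81 ± 0.181 against 0.962 ± 0.128, and H2AC6 at 9.96 ± 3.82 against 5.01 ± 0.234. Of 23 members listed in the table, 6 reached 1 FPKM in all 6 libraries, while H4C8 and H2BC21 passed the filter through the roscovitine libraries and 1 member passed it through DMSO libraries. The list lay 0.71 above all genes when 1 FPKM was asked of all 6 libraries (camera adjusted p = 0.000174) and 0.71 when it was asked of their mean (camera adjusted p = 4.44e-05). Without any filter on low values the list lay 0.047 above all genes, with a camera adjusted p of 0.418, in a range of 9.22e-07 to 0.418 over the alternatives. The rise therefore holds for the members past a filter and not for all that are listed. Histone genes are near-identical copies of one another, so how reads were divided among them is uncertain. Cytosolic ribosomal protein genes fell as a list of 52, of which 48 lay below the median gene and 4 had an unadjusted p under 0.05. Their median lay at -0.30 relative to all genes (camera adjusted p = 0.000175; adjusted p = 0.953 with an estimated correlation). RPL5 was at 129 ± 16.9 FPKM with roscovitine and 204 ± 8.2 with DMSO, RPL22 at 58.8 ± 9.09 against 90.5 ± 3.66, and RPS24 at 60.9 ± 7.79 against 87.8 ± 11.7. This list lost its call without the first roscovitine library, at -0.10 (camera adjusted p = 0.282), and without the third, at -0.13 (camera adjusted p = 0.129), and lay at -0.63 without the second (camera adjusted p = 6.09e-20) and at -0.20 without the first DMSO library (camera adjusted p = 0.0349), in a range of 6.09e-20 to 0.282 over the alternatives.

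**Figure D3:**
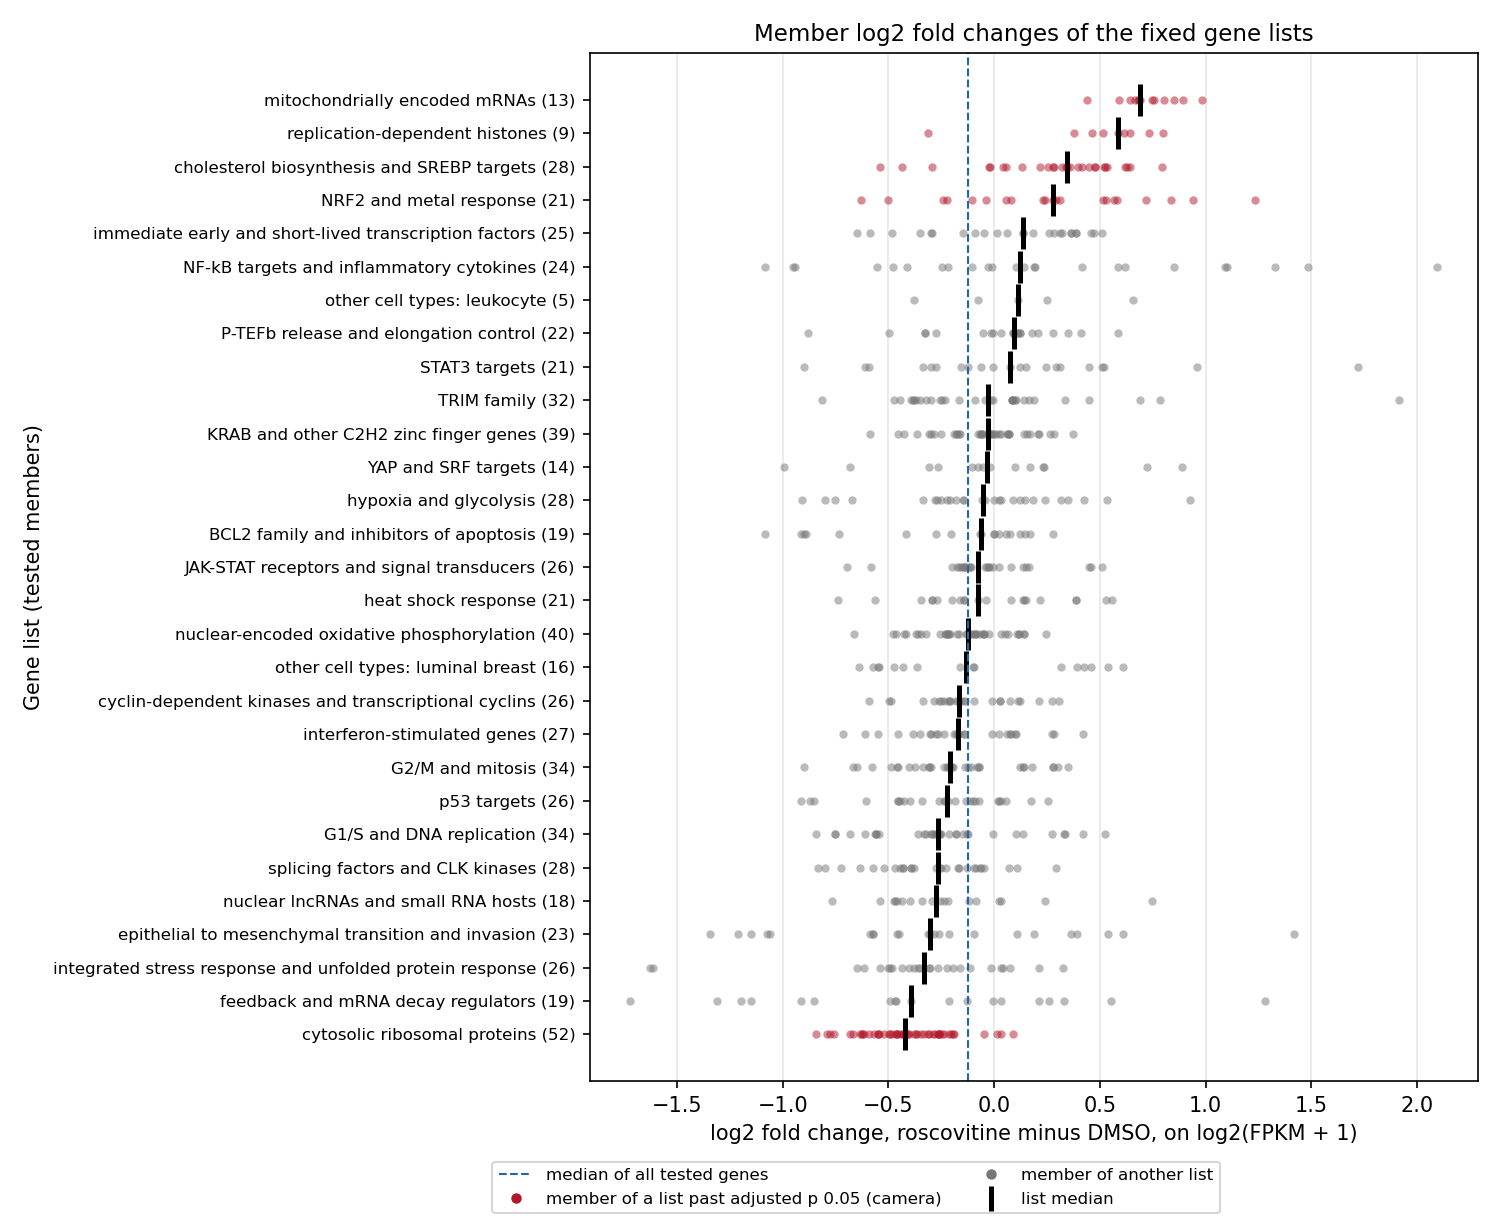
Log2 fold changes, roscovitine minus DMSO on log2(FPKM + 1), of the tested members of 29 gene lists; each point is a gene and each black bar a list median. The dashed line marks the median of all tested genes at -0.12, and red points belong to the 5 lists past an adjusted p of 0.05 by camera.

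Adjusted over the list alone, 6 of the 19 tested feedback and mRNA decay regulators passed by limma, against 0 over all genes tested. ERRFI1, a feedback inhibitor of the EGF receptor (ENSG00000116285), was at 66.98 ± 15.6 FPKM with roscovitine and 234 ± 95.5 with DMSO, SPRED1, an inhibitor of RAS signalling, at 5.04 ± 1.6 against 14.05 ± 4.12, and the pro-apoptotic gene PMAIP1 at 18.2 ± 2.08 against 35.5 ± 6.65. The MAP kinase phosphatase gene DUSP10 went the other way, at 27.6 ± 8.97 against 10.9 ± 4.21 FPKM. As a list these regulators lay at -0.27 relative to all genes (camera adjusted p = 0.19). Camera called them lower without the second DMSO library, at -0.37 (camera adjusted p = 0.0255), and without both second libraries, at -0.50 (camera adjusted p = 0.0222), in a range of 0.0222 to 0.54 over the alternatives. Their median turned to 0.017 without the first DMSO library. Of 24 NF-kB targets and inflammatory cytokines, 2 passed when adjusted over the list alone, LIF at 6.57 ± 0.503 against 13.6 ± 1.26 FPKM and the chemokine gene CCL2 at 3.92 ± 0.446 against 0.858 ± 0.721, and the list lay 0.25 above all genes (camera adjusted p = 0.196). This list was called higher by camera without the first DMSO library, at 0.31 (camera adjusted p = 0.047), and without the third, at 0.43 (camera adjusted p = 8.94e-05), in a range of 8.94e-05 to 0.452. Its median lay below that of all genes, and was not called, in 3 alternatives, at -0.21 without the second DMSO library, -0.27 without both second libraries and -0.21 with library weights. TRAF1, another member, was at 2.84 ± 0.96 against 6.36 ± 1.8 FPKM. Adjusted over the list alone, 1 member each also passed by limma in the histone, NRF2 and TRIM lists, and 0 in the other 24 tested lists. Immediate early and short-lived transcription factors, 25 tested, lay 0.26 above all genes (camera adjusted p = 0.19), with SRF at 20.01 ± 2.01 against 13.8 ± 2.2 FPKM. They were called higher without the third roscovitine library, at 0.45 (camera adjusted p = 0.0257), and without the first DMSO library, at 0.30 (camera adjusted p = 0.0476), in a range of 0.0257 to 0.899. Without a call, their median turned to -0.0053 without the second DMSO library, -0.023 without the second roscovitine library, -0.27 without both second libraries and -0.23 with library weights.

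STAT3 targets lay 0.20 above all genes over 21 tested members, of which 2 were higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.369). The direction of this median turned, to -0.033 without the second DMSO library, -0.20 without both second libraries and -0.015 with library weights. Camera called the list in 0 of 18 alternatives. Among its members the mucin gene MUC1 was at 26.6 ± 11 FPKM with roscovitine and 8.59 ± 5.65 with DMSO, IRF1 at 4.33 ± 0.461 against 7.07 ± 1.16, and the cyclin gene CCND1 at 63.3 ± 11.7 against 97.3 ± 20.1. JAK-STAT receptors and signal transducers, 26 tested, lay 0.048 above all genes (camera adjusted p = 0.488; -0.090 without a filter on low values), with STAT5A at 6.24 ± 1.16 against 4.24 ± 0.212 FPKM. In the TRIM family, 32 tested, 4 members were higher and 1 lower at an unadjusted p under 0.05, and the list lay 0.096 above all genes (camera adjusted p = 0.488) and at -0.0047 without a filter on low values. TRIM26 was at 12.8 ± 0.624 against 7.22 ± 2.2 FPKM and TRIM14 at 3.45 ± 0.978 against 7.15 ± 3.41. Interferon-stimulated genes, 27 tested, lay at -0.048 (camera adjusted p = 0.977), with MX1 at 3.14 ± 0.213 against 2.13 ± 0.607 FPKM. The interferon median turned to 0.070 without the second DMSO library, 0.037 without the second roscovitine library, 0.11 without the third roscovitine library, 0.23 without both second libraries, 0.051 with length and GC trends removed and 0.13 with library weights.

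Cyclin-dependent kinases and transcriptional cyclins, 26 tested, lay at -0.043 relative to all genes (camera adjusted p = 0.889), and 0 members had an unadjusted p under 0.05 by limma or passed by camera's list test. The median of these kinases and cyclins turned to 0.0092 without the second DMSO library, 0.021 without the second roscovitine library, 0.091 without both second libraries, 0.020 with length and GC trends removed and 0.078 with library weights. Genes of CDK9 release and elongation control, 22 tested, lay 0.22 above (camera adjusted p = 0.19), with HEXIM2 at 2.22 ± 0.565 against 1.13 ± 0.195 FPKM and ELL2 at 8.36 ± 3.7 against 15.3 ± 2.9. The G1/S and DNA replication list, 34 tested, lay at -0.14 and the G2/M and mitosis list, 34 tested, at -0.087 (camera adjusted p = 0.369 and 0.723). The replication factor genes RFC4 and RFC3 were at 6.42 ± 0.761 and 7.29 ± 1.81 FPKM with roscovitine against 11.3 ± 4.17 and 13.5 ± 6.13 with DMSO, and the mitotic kinase gene NEK2 at 7.05 ± 2.32 against 11.8 ± 4. Camera called the 2 cell-cycle lists in opposite directions under different alternatives. Without the third DMSO library both were called lower, G1/S at -0.38 (camera adjusted p = 0.00012) and G2/M at -0.31 (camera adjusted p = 0.00324). Without both second libraries both were called higher, G1/S at 0.047 (camera adjusted p = 0.0397) and G2/M at 0.33 (camera adjusted p = 6.36e-06), and with library weights G2/M was too, at 0.34 (camera adjusted p = 7.37e-05). Their adjusted p ranged over the alternatives from 0.00012 to 0.703 for G1/S and from 6.36e-06 to 0.806 for G2/M. Targets of p53, 26 tested, lay at -0.10 with 0 members higher and 4 lower at an unadjusted p under 0.05 by limma (camera adjusted p = 0.126), among them AEN at 1.44 ± 0.128 against 3.49 ± 1.05 FPKM and the death receptor gene TNFRSF10B at 24.8 ± 4.76 against 46.97 ± 13.1. Camera called the p53 targets lower with library weights, at -0.20 (camera adjusted p = 0.0299), and without both second libraries, at -0.18 (camera adjusted p = 0.0345), in a range of 0.0299 to 0.288 over the alternatives. MDA-MB-231 carries mutant p53. The BCL2 family and inhibitors of apoptosis, 19 tested, had a median 0.063 above and a mean of -0.14 relative to all genes (camera adjusted p = 0.488, direction lower), with XIAP at 2.95 ± 1.58 against 5.94 ± 1.53 FPKM and BIRC3 at 5.48 ± 3.18 against 11.7 ± 4.29. The median of this family turned to -0.12 without the second DMSO library, -0.090 without the second roscovitine library, -0.28 without both second libraries, -0.082 with length and GC trends removed, -0.19 with library weights and -0.016 without a filter on low values. None of these was called.

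Genes of the integrated stress and unfolded protein responses, 26 tested, lay at -0.21 relative to all genes (camera adjusted p = 0.19). Camera called this list lower in 3 alternatives, at -0.35 (camera adjusted p = 7.92e-05) without the second DMSO library, at -0.27 (camera adjusted p = 0.00517) with library weights and at -0.30 (camera adjusted p = 0.000671) without both second libraries, in a range of adjusted p of 7.92e-05 to 0.45. PSAT1, a serine synthesis enzyme, was at 13.5 ± 1.78 FPKM with roscovitine and 48.3 ± 29.2 with DMSO, and ASNS, asparagine synthetase, at 4.57 ± 0.536 against 21.1 ± 19.7, where the third DMSO library held 43.8 FPKM. The heat shock list, 21 tested, lay 0.046 above all genes (camera adjusted p = 0.488), with HSPB1 at 87.6 ± 10.1 against 59.6 ± 11.2 FPKM. The heat shock median turned to -0.0015 without the first DMSO library, -0.0030 without the third DMSO library, -0.042 without the first roscovitine library and -0.10 without a filter on low values. Hypoxia and glycolysis genes, 28 tested, had a median 0.073 above all genes (camera adjusted p = 0.72), while the glucose transporter gene SLC2A3 was at 6.03 ± 0.558 against 12.3 ± 2.31 FPKM and hexokinase HK2 at 9.07 ± 1.43 against 15.1 ± 3.01. The hypoxia median turned to -0.16 without the second DMSO library, -0.057 without the second roscovitine library, -0.36 without both second libraries, -0.23 with library weights and -0.034 without a filter on low values, of which only that without both second libraries was called (camera adjusted p = 0.00123, in a range of 0.00123 to 0.991 over the alternatives). Genes of epithelial to mesenchymal transition and invasion, 23 tested, lay at -0.18 with 0 members higher and 5 lower at an unadjusted p under 0.05 by limma (camera adjusted p = 0.369). The integrin gene ITGA5 was at 17.1 ± 4.2 against 37.1 ± 10.4 FPKM and the matrix protein gene TGFBI at 11.4 ± 3.86 against 25.5 ± 10.2. YAP and SRF targets, 14 tested, lay 0.089 above (camera adjusted p = 0.488), with MYL9 and AXL at 40.1 ± 9.01 and 137 ± 14.98 FPKM against 21.03 ± 3.5 and 84.02 ± 22.6, and ANKRD1 at 198 ± 79.9 against 387 ± 103. Splicing factors and CLK kinases, 28 tested, lay at -0.14 (camera adjusted p = 0.19), with HNRNPA1 at 111 ± 37.8 against 191 ± 31.9 FPKM. Camera called them lower without the third roscovitine library, at -0.26 (camera adjusted p = 0.0193), and without the first DMSO library, at -0.28 (camera adjusted p = 0.0174), in a range of 0.0174 to 0.703. The splicing median turned to 0.071 without the second roscovitine library, 0.14 without both second libraries and 0.052 with library weights. Nuclear long non-coding RNAs and small RNA hosts, 18 tested, lay at -0.15 and C2H2 zinc finger genes, 39 tested, 0.095 above (camera adjusted p = 0.493 and 0.488), with DANCR at 4.71 ± 0.455 against 2.4 ± 0.201 FPKM and ZNF79 at 2.91 ± 0.254 against 2.01 ± 0.0749. The zinc finger genes were called higher without the second roscovitine library, at 0.24 (camera adjusted p = 0.00024), with library weights, at 0.20 (camera adjusted p = 0.00138), with length and GC trends removed, at 0.21 (camera adjusted p = 0.00238), and without both second libraries, at 0.29 (camera adjusted p = 0.000494), in a range of 0.00024 to 0.982. Their median turned to -0.0017 without the first DMSO library, -0.0022 without the first roscovitine library and -0.043 without a filter on low values. The nuclear RNAs were called lower with library weights, at -0.35 (camera adjusted p = 0.0434), in a range of 0.0434 to 0.841.

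Markers of other cell types were also measured. Luminal breast genes, 16 tested, lay at -0.0079 relative to all genes (camera adjusted p = 0.605), with 6 members at a log2 fold change above 0 and 10 below. ERBB2 was at 7.22 ± 1.7 against 5.06 ± 0.47 FPKM and GATA3 at 1.64 ± 0.28 against 1.11 ± 0.164, whereas ERBB3 was at 1.11 ± 0.214 against 2.17 ± 0.944 and MLPH at 10.6 ± 4 against 15.7 ± 4.35. Camera called this list lower without the second DMSO library, at -0.66 (camera adjusted p = 0.0446), and without both second libraries, at -0.90 (camera adjusted p = 0.000456), in a range of adjusted p of 0.000456 to 0.973 over the alternatives. It lay above all genes, without a call, at 0.14 without the first DMSO library, 0.11 without the third DMSO library, 0.058 without the first roscovitine library, 0.0057 without the third roscovitine library and 0.024 with a pseudocount of 0.1. Leukocyte genes, 5 tested, lay 0.23 above all genes (camera adjusted p = 0.675). The leukocyte median turned to -0.33 without the second DMSO library, -0.079 without the second roscovitine library, -0.25 without both second libraries and -0.27 with library weights. Erythroid and fibroblast or endothelial markers had too few members for the list test, with 3 and 4 tested. Of the erythroid markers, ANK1 was at 5.11 ± 1.82 against 1.68 ± 0.60 FPKM and the transferrin receptor gene TFRC, which dividing cells of many types express, at 34.7 ± 15.7 against 23.1 ± 4.93. The globin genes HBE1 and HBG2, chosen after their values were seen, had lower means with roscovitine, at 0.359 against 1.26 and 0.146 against 0.471 FPKM, and were not tested because they did not pass the filter.

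The authors' deposited table marked 424 genes as significant, 230 higher and 194 lower with roscovitine, all with a q-value of at most 0.0499 and an absolute log2 fold change of at least 1.01. Of those, 218 passed the filter on low values here, and all 218 had an unadjusted p under 0.05 by limma and the same direction, while 0 passed the adjusted threshold. The groups did not overlap for 214 of the 218. The other 206 genes marked in the authors' deposited table did not reach 1 FPKM in 3 libraries, and 27 of the 424 were listed at 0 in all libraries of one treatment. Across all tested genes, the log2 fold changes here and in the authors' deposited table had a Spearman correlation of 0.981, over genes that are not independent replicates. Both come from the same 6 libraries, and the marked genes were chosen for large changes in them. The shared direction, the lack of overlap and the correlation were therefore largely fixed in advance and are no independent support. Of the 24 genes with the smallest p, 23 were marked significant in the authors' deposited table, the exception being ADORA2A with a q-value of 0.269, and neither TRIM32 nor STAT3 was, with q-values of 0.991 and 0.824.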

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

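Library weights, the 4 scalings, the robust prior, the removal of length and GC trends, leaving out both second libraries, and 2 filters on all 6 libraries for the 5 lists past the threshold were chosen only after the data were seen. Alternatives that had been chosen for read counts were not run: DESeq2, voom, edgeR with other scaling factors and the non-robust dispersion. The planned fits without a scaling factor and on the table's own values are the analysis itself. Of 1946 values for 110 named genes over 18 alternatives, 1778 kept their direction and side of the threshold, 137 gained a call and 31 changed sign, in 9 genes. Of 530 list values 435 kept both, 22 gained a call, 4 lost one and 69 changed sign, 7 of these past an adjusted p of 0.05 by camera: G1/S and DNA replication, G2/M and mitosis, hypoxia and glycolysis and nuclear-encoded oxidative phosphorylation without both second libraries, G2/M and mitosis and nuclear-encoded oxidative phosphorylation with library weights, nuclear-encoded oxidative phosphorylation without roscovitine 2. Without a change of sign, calls were gained without roscovitine 2 KRAB and other C2H2 zinc finger genes at 0.24, without roscovitine 3 immediate early and short-lived transcription factors at 0.45 and splicing factors and CLK kinases at -0.26, without DMSO 1 immediate early and short-lived transcription factors at 0.30, NF-kB targets and inflammatory cytokines at 0.31 and splicing factors and CLK kinases at -0.28, without DMSO 2 feedback and mRNA decay regulators at -0.37, integrated stress response and unfolded protein response at -0.35 and luminal breast genes at -0.66, without DMSO 3 G1/S and DNA replication at -0.38, G2/M and mitosis at -0.31 and NF-kB targets and inflammatory cytokines at 0.43, with library weights p53 targets at -0.20, integrated stress response and unfolded protein response at -0.27, KRAB and other C2H2 zinc finger genes at 0.20 and nuclear lncRNAs and small RNA hosts at -0.35, with length and GC trends removed KRAB and other C2H2 zinc finger genes at 0.21, without both second libraries feedback and mRNA decay regulators at -0.50, p53 targets at -0.18, integrated stress response and unfolded protein response at -0.30, KRAB and other C2H2 zinc finger genes at 0.29 and luminal breast genes at -0.90. Except where the construction is named, the cause was not tested. With an adjusted threshold of 0.01 limma again called 0 genes. Depth is unknown, so what it limits could not be stated.

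With library weights limma called 454 genes higher and 969 lower, 88 and 224 of them at least 2-fold, 203 of them also marked in the authors' deposited table, and 1163 and 2305 genes had an unadjusted p under 0.05. With both second libraries left out it called 284 and 786, 93 and 305 at least 2-fold, 141 of them marked in the authors' deposited table, with 1101 and 1923 at an unadjusted p under 0.05. Both called all tested genes of the 24 with the smallest p, but weights of 0.164 and 0.418 nearly leave out the second libraries, so these fits are not independent. Camera called 5 lists lower with weights, and 7 higher and 7 lower without both second libraries, and an estimated correlation, used only with all 6 libraries at equal weight, gave 0 and 0. With weights, the log2 fold changes that changed sign were CD68 at 0.064, CDK2 at 0.030, CDK5 at -0.16, KRT18 at -0.15 and TFF1 at -1.29, and the list medians relative to all genes were BCL2 family and inhibitors of apoptosis at -0.19, cyclin-dependent kinases and transcriptional cyclins at 0.078, G1/S and DNA replication at 0.090, G2/M and mitosis at 0.34, hypoxia and glycolysis at -0.23, immediate early and short-lived transcription factors at -0.23, interferon-stimulated genes at 0.13, NF-kB targets and inflammatory cytokines at -0.21, nuclear-encoded oxidative phosphorylation at -0.31, leukocyte genes at -0.27, splicing factors and CLK kinases at 0.052 and STAT3 targets at -0.015. Without both second libraries they were CDK5 at -0.24, CDK9 at -0.0027, KRT18 at -0.25 and TFF1 at -1.79, of which only TFF1 passed the adjusted threshold of limma, and for lists BCL2 family and inhibitors of apoptosis at -0.28, cyclin-dependent kinases and transcriptional cyclins at 0.091, G1/S and DNA replication at 0.047, G2/M and mitosis at 0.33, hypoxia and glycolysis at -0.36, immediate early and short-lived transcription factors at -0.27, interferon-stimulated genes at 0.23, NF-kB targets and inflammatory cytokines at -0.27, nuclear-encoded oxidative phosphorylation at -0.40, leukocyte genes at -0.25, splicing factors and CLK kinases at 0.14 and STAT3 targets at -0.20. With length and GC trends removed 1 gene was higher, at least 2-fold and marked in the authors' deposited table, and the changed signs were CDK5 at -0.14, CDK7 at 0.024 and CDK9 at -0.12, with BCL2 family and inhibitors of apoptosis at -0.082, cyclin-dependent kinases and transcriptional cyclins at 0.020, G2/M and mitosis at 0.020 and interferon-stimulated genes at 0.051.

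With no filter 1187 genes were higher and 1660 lower at an unadjusted p under 0.05, and with at least 5 FPKM 325 and 503, because more or fewer genes were tested. Without a filter the changed list signs were BCL2 family and inhibitors of apoptosis at -0.016, heat shock response at -0.10, hypoxia and glycolysis at -0.034, JAK-STAT receptors and signal transducers at -0.090, KRAB and other C2H2 zinc finger genes at -0.043, nuclear-encoded oxidative phosphorylation at -0.11 and TRIM family at -0.0047, and with a pseudocount of 0.1 luminal breast genes at 0.024. Lower genes at an unadjusted p under 0.05 numbered 560 with median-of-ratios, 544 with upper-quartile, 558 with scaling without mitochondrially encoded genes and 541 with quantile normalization, which had 873 higher. The log2 fold changes that then changed sign were CD68 at 0.019 and SOCS3 at 0.082 with median-of-ratios, CD68 at 0.020 and SOCS3 at 0.082 with upper-quartile, SOCS3 at 0.050 without mitochondrially encoded genes and CD68 at 0.028 and SOCS3 at 0.079 with quantile normalization, and under quantile normalization nuclear-encoded oxidative phosphorylation at -0.029. That normalization sets the highest-ranked genes to nearly equal values in all libraries, which bears on mitochondrially encoded mRNAs by construction.

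Leaving out 1 library at a time gave 0 genes higher in each fit and 0 to 1 lower at an adjusted p of 0.05, also with a 2-fold change, with 340 to 583 higher and 479 to 1291 lower at an unadjusted p under 0.05, 4 to 6 lists higher and 0 to 4 lower. Over these fits log2 fold changes ranged for AGR2 from -1.34 to 0.010, CD68 from -0.29 to 0.21, SOCS3 from -0.43 to 0.24, TFF1 from -1.20 to 1.37, CDK5 from -0.22 to 0.20 and KRT18 from -0.058 to 0.70. List medians relative to all genes ranged for feedback and mRNA decay regulators from -0.37 to 0.017, heat shock response from -0.042 to 0.17, KRAB and other C2H2 zinc finger genes from -0.0022 to 0.24, luminal breast genes from -0.66 to 0.14, BCL2 family and inhibitors of apoptosis from -0.12 to 0.13, cyclin-dependent kinases and transcriptional cyclins from -0.11 to 0.021, G1/S and DNA replication from -0.38 to 0.15, G2/M and mitosis from -0.31 to 0.16, hypoxia and glycolysis from -0.16 to 0.20, immediate early and short-lived transcription factors from -0.023 to 0.45, interferon-stimulated genes from -0.17 to 0.11, NF-kB targets and inflammatory cytokines from -0.21 to 0.43, nuclear-encoded oxidative phosphorylation from -0.33 to 0.12, leukocyte genes from -0.33 to 0.64, STAT3 targets from -0.033 to 0.37 and splicing factors and CLK kinases from -0.28 to 0.071.

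Whether the replicate numbers pair the libraries could not be told. Deviations from the group means correlated at -0.604, -0.429 and 0.00993 for the same numbers. All 3 roscovitine libraries correlated best with a DMSO library of another number. However, the deviations are centred within 3 libraries per treatment, and the second libraries lay at opposite ends of the first component. Such values can arise with or without a pairing. With the replicate number as a block, 344 genes were higher and 518 lower at an unadjusted p under 0.05 and 0 passed, with a smallest adjusted p of 0.615 by limma.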

Other observations

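The pathway tests, the lysosome pathway and the luminal genes were chosen only after the data were seen, as were the tests of the second roscovitine library and of length and GC content on the lists. The splits of the libraries and the first 2 tests of the lysosome pathway were set before their results were seen, and its test without the second DMSO library was added later.

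Genes annotated to the lysosome in the table's KEGG column lay higher with roscovitine relative to all genes. Of 106 tested genes, 27 were higher and 10 lower with no overlap between the groups, where chance gives 10% in all and 966 of all 11733 tested genes were higher and 1514 lower without overlap, and the pathway median lay 0.22 above all genes (camera adjusted p = 0.00611; p = 0.104 and adjusted p = 0.994 with an estimated correlation). CTSD, the aspartic protease cathepsin D, was at 1394 ± 675 FPKM with roscovitine and 549.7 ± 129 with DMSO (SD, n = 3). CTSA, which encodes cathepsin A, was at 74.1 ± 14.1 against 39.9 ± 2.83 FPKM, the sialidase gene NEU1 at 26.9 ± 5.47 against 14.1 ± 2.65, CLN3 at 3.94 ± 0.979 against 1.87 ± 0.204, and the proton pump subunit gene ATP6V0A4 at 3.88 ± 1.25 against 1.28 ± 0.432. None of these 5 genes passed the adjusted threshold of limma. Among 289 KEGG pathways with at least 10 tested members, 12 were higher and 3 lower by camera and 0 passed with an estimated correlation. The smallest adjusted p belonged to disease pathways, Staphylococcus aureus infection at 0.85 above all genes (adjusted p = 0.000369 by camera), rheumatoid arthritis at 0.28 (adjusted p = 0.000854) and graft-versus-host disease at 0.65 (adjusted p = 0.00314). Their members included the complement gene C3 at 47.3 ± 22.8 against 11.7 ± 9.41 FPKM, the antigen presentation gene HLA-DRA at 17.5 ± 11.1 against 7.73 ± 0.865 and the chemokine gene CXCL1 at 45.4 ± 11.8 against 17.8 ± 17.9, chosen after their values were seen. With 1 library left out at a time their log2 fold changes ranged from 1.31 to 2.96, 0.47 to 1.24 and 0.85 to 3.01. Phagosome genes lay 0.23 above all genes (adjusted p = 0.00611 by camera) and steroid biosynthesis genes 0.46 above (adjusted p = 0.037 by camera), while ribosome genes lay at -0.21 (adjusted p = 0.0134 by camera) and proteasome genes at -0.22 (adjusted p = 0.037 by camera). Each of the 15 pathways lost its call by camera without at least 1 of the 6 libraries. The Staphylococcus aureus pathway lost it at 0.54 without the second roscovitine library and 0.65 without the second DMSO library, rheumatoid arthritis at 0.13 without the second DMSO library, and graft-versus-host disease at 0.36 without the second roscovitine library and 0.47 without the second DMSO library, while rheumatoid arthritis lay at 0.43 without the third DMSO library. Phagosome genes lost it at 0.20 without the second DMSO library and steroid biosynthesis at 0.36 without the first roscovitine library, 0.40 without the third roscovitine library and 0.23 without the second DMSO library. Ribosome genes lost it at -0.050 without the first roscovitine library, -0.072 without the third roscovitine library and -0.13 without the first DMSO library and proteasome genes at -0.22 without the first roscovitine library, -0.13 without the third roscovitine library, -0.18 without the first DMSO library and -0.17 without the second DMSO library, but without the second roscovitine library they lay at -0.52 and -0.35.

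The luminal genes TFF1 and AGR2, a secreted trefoil peptide and a disulfide isomerase, varied widely between libraries of one treatment. Of 18 listed luminal genes 16 reached 1 FPKM in at least 1 library, up to 360.4 FPKM for KRT18, as did 6 of 13 leukocyte genes, up to 40.5 FPKM for CD68, 5 of 16 fibroblast or endothelial genes, up to 6.71 for COL6A3, and 4 of 13 erythroid genes, up to 49.5 for TFRC. The luminal genes that did not were ESR1, at up to 0.00442 FPKM, and FOXA1, at up to 0.0331, and both were at 0 in the second roscovitine library. TFF1 was at 15.02, 70.7 and 27 FPKM with roscovitine and at 64.2, 1.32 and 81.4 with DMSO. AGR2 was at 23.1, 44.5 and 37.9 FPKM with roscovitine and at 93.7, 13.5 and 81.9 with DMSO. Without both second libraries limma called both lower, TFF1 at a log2 fold change of -1.79 (adjusted p = 0.00697, in a range of 0.00697 to 0.973 over the alternatives) against 0.46 in all 6 libraries, and AGR2 at -1.53 (adjusted p = 0.00842, in a range of 0.00842 to 0.997) against -0.47. TFF1 also turned to -0.13 without the second roscovitine library and -1.20 without the second DMSO library, and AGR2 to 0.010 without the first DMSO library.

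The lysosome pathway kept more than 50% of its shift when length and GC trends were removed, at 0.129 (camera adjusted p = 0.00529), and without the second roscovitine library, at 0.133 (camera adjusted p = 0.0178). Neither of these therefore accounts for the whole shift. Without the second DMSO library the pathway lay at 0.11, just under 50% of its shift of 0.221. It then lost its call (camera adjusted p = 0.39, in a range of 0.000683 to 0.994 over all its alternatives). This value is close to the 0.129 and 0.133 above, so the bound of 50% separates these tests only narrowly. The shift may rest in part on each of the 3. That roscovitine raised lysosomal transcripts within 1 hour is a hypothesis, which the lost call and the estimated correlation (p = 0.104) leave open.

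The second roscovitine library differed from the mean of the other roscovitine libraries with an SD across genes of 0.684 on the log2 scale. Transcript length and GC content accounted for 46.2% of the variance of this difference, against 36% for the first roscovitine library. The mean that the first library was set against includes the second, so the 36% is not independent of the 46.2%. This share was replaced by the test below after it was seen. In the second roscovitine library, genes with transcripts of up to 887 nt lay at a median of 0.17 and those of at least 2870 nt at -0.44 relative to the other roscovitine libraries. Lower depth stays open: 1 fragment was worth 1.02 times the median of the other libraries by a measure that did not recover reads. That measure could not show a large difference in depth. This library held the fewest genes above 0, 23635 against 24666 to 25337 in the others. With length and GC trends removed its SD was 0.502, or 1.02 times the highest SD of the DMSO libraries, 0.494 in the second, which stood apart as well, and this lay between the bounds set for and against this explanation, so RNA fragmentation or library preparation may contribute. Luminal genes then still lay 0.53 above the other roscovitine libraries, leukocyte genes 0.24, fibroblast or endothelial genes 0.36 and erythroid genes -0.074, so cells of another type or state also stay open, as does a response to roscovitine that differed between cultures, which was not tested.

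With length and GC trends removed the 5 lists past the threshold stayed past it, at 0.963 for mitochondrially encoded mRNAs, 0.382 for cholesterol and SREBP targets, 0.632 for histones, 0.336 for the NRF2 and metal response and -0.354 for ribosomal proteins, relative to all genes. These trends were therefore not the whole cause of any of the 5. Roscovitine remains a candidate cause, as do differences between cultures that happen to follow the groups.

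The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. By limma 0 genes passed in the real split and in all 10 splits, the highest of the others being 0, and 1438 genes had an unadjusted p under 0.05 against a highest other of 1794, with 2 splits at or above the real count. Camera with its preset correlation called 5 lists in the real split and up to 18 in the others, and all 10 splits called at least as many as the real one. With library weights 1423 genes passed in the real split and 4248 in the highest other, with 4 splits at or above the real count. Camera's calls at the preset correlation therefore do not set the real grouping apart. The split with 1794 genes was also the one with 18 lists. It set roscovitine 1 and 3 with DMSO 2, so it differed from the real grouping only in the place of the second library of each treatment. Those are the libraries that stood apart from the rest. Why other splits gave higher counts was not tested. The weights were estimated anew in each split, and what they add to these counts was not tested.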
